A study of Danio rerio with 4 samples.

How the data were processed

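The data were 4 libraries of testis RNA from AB zebrafish, 1 each for control, DBP, DiBP and DBP+DiBP. Per the labels' protocols, testes were snap frozen, RNA was extracted with the RNeasy Mini Kit, libraries were made with the NEBNext Ultra kit from 3 μg of RNA, and paired ends were read on an Illumina sequencer. Per the labels the fish were male, while the series' design text calls them female; the tissue was labelled testis throughout. Per the submitters' processing notes, HISAT2, HTSeq 0.6.1 and the GRCz10 assembly were used, with no account of which made the deposited values. No dose, read number, strand setting or pooling of fish was stated. Each sample title carries the number 2, whose meaning is not stated, so whether other libraries were made is unknown.

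The authors deposited 1 file per library with 1 value per gene, taken here as FPKM (fragments scaled to transcript length and library size), although no header or label names the unit. This was inferred from the values: they were not whole, their totals differed between libraries, and among low values the ratio of 2 libraries piled up at a constant and its simple multiples, as for fragments divided by library depth. Those constants also gave the relative depths. Each file held 49610 identifiers, 35066 Ensembl genes and 14544 assembled loci (MSTRG). The table of gene names that came with the data gave a symbol to 26996 Ensembl genes. Its symbols in capitals lack the letter that tells duplicated zebrafish copies apart, so 2 genes can carry 1 symbol. No genome came with the data, so no coordinates are given. Of the identifiers 4775 were at 0 in every library, and 3636 shared all their values with another identifier. The latter were merged into 1484 features, and names drawn from them are uncertain.

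The design written before the data were examined foresaw counts. Because the files held FPKM, its fallback was used: log2(FPKM + 1), features with a mean FPKM of at least 1 over the 4 libraries (23405 of 42683 not all at 0; 15843 Ensembl and 7562 assembled), and a 2-fold rule with no interval and no p-value. Values were compared as deposited, with no further scaling. The comparisons were each exposed library against control, DiBP against DBP, and DBP+DiBP against each single exposure. A feature was shared when it passed 2-fold the same way in all 3 exposed libraries. Departure from additivity was the log2 ratio of DBP+DiBP to control minus the sum of the DBP and DiBP ratios.

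Features were tested across libraries with limma 3.58.1 in R 4.3.3, with a trend in the prior variance and Benjamini-Hochberg adjustment at 0.05. The fits were control against the 3 exposed libraries (2 residual degrees of freedom), a model with additive DBP and DiBP terms (1 residual degree of freedom) and the difference of those terms. The first treats different exposures as replicates of each other, and the others treat any departure from additivity as noise. Each other library was also set against the remaining 3. On simulated data with a noise SD of 0.3, control against the 3 exposed libraries recovered 8 of 100 features with a log2 change of 1 and 90 of 100 with a change of 2, with 0 of 23005 unchanged features called. The additive DBP term recovered 19 and 99 of 100, with 2 unchanged features called. With noise as large as between the exposed libraries, both recovered 0 of 100 at each size. In these simulations the changed features were drawn only from those with a mean log2(FPKM + 1) of at least 3. Recovery among weaker features is therefore not known. The 2-fold rule was checked for its counting alone, on equal libraries without noise in which 200 features were set 4-fold higher in DBP. It recovered 200 of 200 among 6761 features with 0 others. Without noise this outcome was fixed, so it says nothing about false calls in real libraries.

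The 29 gene lists, written before the data were examined, covered testis cell types (Leydig, Sertoli, spermatogonia, meiosis, spermatids), steroid and estrogen action, xenobiotic and lipid metabolism, stress and immune responses, other tissues, and housekeeping groups. Members were matched to the files by symbol or symbol pattern, where none matched by the symbol without its copy letter, and only then by synonym. Where the copy letter was dropped, every copy with the symbol counted, so lists can hold copies that were not meant. A list's median log2 ratio was placed among 10000 random lists of equal size matched on mean expression. Named genes followed a rule fixed beforehand. For each exposed library against control, these were the 8 highest and 8 lowest ratios among 2-fold features with a mean of at least 5 FPKM and a non-provisional symbol. For the isomers the rule took 5 of each, for the shared set 8 of each by mean ratio, and it added fixed hormone and testis genes and up to 4 members per list; other genes serve as examples of their lists. Further marker lists of gut cells, pancreas, liver and muscle were written after the first results were seen. Agreement between ratios to the shared control was set beside 100 simulations of unchanged libraries. Their noise was each feature's SD over all 4 libraries, so it includes differences between exposures.

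The alternatives tried were median-of-ratios, equal-total and upper-quartile scaling, no filter, a mean of at least 5 FPKM, pseudocount 0.1, and leaving out each exposed library. Ensembl genes only, no merged features, no immediate early or heat shock genes, and a filter without the DBP+DiBP library were chosen after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the comparisons.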

Results

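RNA was sequenced from the testes of adult AB zebrafish (wild type, 5 months old) after 30 days of exposure to dibutyl phthalate (DBP), to diisobutyl phthalate (DiBP), or to both together (DBP+DiBP), beside an unexposed control. DBP and DiBP are plasticizers and structural isomers that differ in the butyl chains of the ester, linear in DBP and branched in DiBP. The labels give no doses. Each of the 4 groups was 1 library, so no value below has a replicate check, and every fold describes these libraries. Expression was given as FPKM (a unit read from the values, since the files do not state it) for 49610 genes and assembled loci, of which 23405 features averaged at least 1 FPKM and were compared. The FPKM values summed to 604779 in control, 575737 in DBP, 547485 in DiBP and 605447 in DBP+DiBP, and read numbers were not given. The spacing of low values put the sequencing depth relative to control at 1.05 for DBP, 1.103 for DiBP and 1.09 for DBP+DiBP. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.918 between control and DBP, 0.935 between control and DiBP and 0.944 between DBP and DiBP. It was lower for every pair with DBP+DiBP, at 0.859 with control, 0.832 with DBP and 0.843 with DiBP. A feature is called higher or lower when log2(FPKM + 1) differed by at least 2-fold, a scale that understates the folds of weakly expressed genes. Lists of genes were fixed before the data were examined, and each list's median is placed as a percentile among 10000 random lists matched on expression.

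The DBP library was compared with control to ask how the testis transcriptome differed after exposure to this phthalate. Immediate early genes, the transcription factors and phosphatases that cells induce soon after a stimulus, were lower in DBP as a group. Of 38 measured members 32 were lower and 0 higher, with a median log2 ratio of -2.04 (percentile 0). FOSB, an AP-1 subunit, stood at 2.62 FPKM in DBP and 36.7 in control, the phosphatase DUSP5 at 2.304 and 35.6, and CEBPB at 14.1 and 136. Genes of the unfolded protein response and heat shock were lower in 12 of 48 members and higher in 0 (median -0.52, percentile 0). The inducible chaperone hsp70.3 had 4.61 FPKM in DBP and 165 in control, hsp70l 12.99 and 161, and HSPB1 6.13 and 74.6. Genes of inflammation and complement were lower in 10 of 41 and higher in 3, with a median of -0.07 (percentile 10.2). Among them the chemokine cxcl18b had 7.86 FPKM against 264 in control, the prostaglandin synthase PTGS2 0.694 against 33.3, and cxcl8a was listed at 0 in DBP and at 11.3 in control. In the list of p53, DNA damage and apoptosis genes, 6 of 58 were lower and 0 higher (median -0.08), among them the survival factor mcl1a with 75.8 FPKM in DBP and 363 in control.

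Germ cell genes of late stages had positive medians in DBP against control, with few past 2-fold. Of 51 genes of spermatids and the flagellum 6 were higher and 2 lower, with a median of 0.56 (percentile 100); the axonemal genes CFAP157 and dnah9 had 13.7 and 21.4 FPKM in DBP and 2.15 and 6.83 in control. Of 25 meiosis genes 1 was higher, the cohesin subunit stag3 (41.3 against 13.3 FPKM), and the median was 0.37 (percentile 99.95). The 10 spermatogonia genes all stayed under 2-fold, with a median of -0.02 that turned positive under at least 1 of 3 other scalings. Steroidogenesis and Leydig cell genes had a median of 0.33 (percentile 98.4), with 2 of 16 higher and 0 lower. The cortisol-inactivating HSD11B2 was at 16.3 against 6.18 FPKM, and cyp11c1, the hydroxylase that leads to 11-ketotestosterone, at 105 against 53.3 (log2 ratio 0.97). Sertoli cell genes had a median of -0.40 (percentile 0.05), with 3 of 15 lower, among them the keratin krt18a.1 at 65.6 against 409 FPKM. Another of the lower was tfa (2.08 against 16.8 FPKM), which also serves as a hepatocyte marker below. Genes for cytosolic ribosomal proteins had a median of -0.46 (80 members, percentile 0), and RPL29 alone passed 2-fold. Stromal, vessel and smooth muscle genes had a median of 0.33 (percentile 99.7), with 2 of 27 higher and 2 lower.

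Over all features, 1564 were higher and 1054 lower in DBP than in control, with a median log2 ratio of 0.05. The highest ratios among well annotated genes belonged to msnb (51.3 FPKM in DBP, 0.732 in control), endou2 (36.5 and 0.448), mir202 (23.3 and 0.543), FBXO42 (80.8 and 5.02), taok2a (11.7 and 0.358), slc22a13a (8.12 and 0.106) and OGA (21.7 and 1.81). The MHC class II gene mhc2dab had 18.2 FPKM in DBP and was listed at 0 in control. Beside the genes above, the lowest ratios were those of TIMP2 (0.722 and 28.2), the acute phase gene SAA2 (1.52 and 37.2), ifitm1 (1.89 and 42.3) and EDC4 (1.83 and 33.6). The lowest also held hsp70.1, whose values are shared with another gene and so are uncertain (3.84 and 77.9).

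The DiBP library was compared with control to ask the same of the branched isomer. Some heat shock genes were higher in DiBP: hsp70l had 2342 FPKM against 161 in control, hsp70.3 1511 against 165 and the co-chaperone dnajb1b 142 against 32.7. These were part of the 6 of 48 unfolded protein response and heat shock genes that were higher, with 2 lower, and the list's median was -0.06 (percentile 9.88), which turned positive under at least 1 other scaling. Mitochondrially encoded genes were lower as a group, 7 of 10 past 2-fold, with a median of -1.31 (percentile 0) beside -0.54 in DBP. MT-ND6 had 255 FPKM in DiBP and 755 in control, and MT-ND1 544 and 1446. Genes for cytosolic ribosomal proteins had a median of -0.61 (percentile 0), with 4 of 80 lower, such as RPS12 at 1213 against 2746 FPKM. Immediate early genes were lower in 9 of 38 and higher in 0, with a median of -0.38 (percentile 0); FOSB was at 11.2 FPKM and DUSP5 at 11.4, against the control values of 36.7 and 35.6.

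Of the genes of hormone production, STAR, which moves cholesterol into mitochondria, was lower in DiBP at 64.6 FPKM against 132 in control (log2 ratio -1.02). The ferredoxin fdx1b was at 12.3 against 33.6, and the Leydig cell hormone insl3 at 1044 against 2072 (log2 ratio -0.99). The steroidogenesis and Leydig cell list had 1 member higher and 2 lower of 16 and a median of -0.18 (percentile 4.59). Sertoli cell genes were lower in 5 of 15 (median -0.44, percentile 0.04), among them WT1 at 2.49 against 6.67 FPKM, while amh, the anti-Müllerian hormone, was at 42.7 against 79.1. The lower members of this list include tfa, also a hepatocyte marker. Spermatid and flagellum genes had a median of 0.46 (percentile 100) with 5 of 51 higher and 1 lower, led by dnah9 at 21.4 against 6.83 FPKM and DNAI1 at 40.6 against 13.9. Meiosis genes had a median of 0.22 (percentile 95.1), with stag3 again the 1 member higher at 54.0 against 13.3 FPKM. Spermatogonia genes had a median of -0.33 (percentile 1.87), with all 10 under 2-fold. The list of liver, pancreas, gut and muscle genes split, with 8 of 44 higher and 9 lower (median -0.33, percentile 0). Among skeletal muscle markers, a list added after the data were seen, 8 of 19 were higher in DiBP and 0 lower (median 0.87, percentile 100), and an added list of 18 hepatocyte markers had a median of -0.44 (percentile 0.04), with 1 higher and 3 lower. Fixed lists already held 14 of these muscle and 11 of these hepatocyte genes, so the added lists largely restate that split. The muscle gene pvalb2 had 19.1 FPKM in DiBP and 3.54 in control, whereas the liver and gut genes tfa, apoa1b and FABP6 had 0.409, 0.924 and 0.430 in DiBP and 16.8, 12.4 and 6.45 in control.

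Over all features, 1077 were higher and 903 lower in DiBP than in control, with a median log2 ratio of -0.01. With library totals made equal the split was 1350 and 732. Beside the heat shock genes, the highest ratios were those of endou2 (51.8 FPKM in DiBP), msnb (41.1), mhc2dab (15.4), pnrc1 (61.9 against 5.996 in control) and taok2a (9.01). The lowest were those of SAA2 (1.33 FPKM), lgals2b (0.805 against 23.9), ifitm1 (2.96), the pancreatic elastase cela1.3 (1.01 against 13.4) and PMP22 (3.101 against 28.0). PLAC8 was listed at 0 in DiBP and at 5.69 in control.

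The DBP+DiBP library was compared with control to ask about joint exposure. Genes of the gut and liver were among those with the highest ratios in DBP+DiBP. FABP6, the ileal bile acid binding protein, had 2323 FPKM against 6.45 in control, the intestinal FABP2 194 against 0.467, the brush border protein VIL1 51.8 against 0.760, and the apolipoprotein apoa1a 461 against 5.06. In the list of liver, pancreas, gut and muscle genes 26 of 44 were higher and 3 lower, with a median of 1.12 (percentile 100). Leukocyte genes were higher in 17 of 27 and lower in 0 (median 1.499, percentile 100), such as the lysozyme gene lyz at 181 against 7.58 FPKM and the macrophage receptor marco at 27.7 against 1.77. Stromal, vessel and smooth muscle genes were higher in 11 of 27 and lower in 1 (median 0.73, percentile 100), with DES at 34.3 against 3.50 FPKM and acta2 at 152 against 29.1. Complement genes were among the 15 of 41 inflammation and complement genes that were higher, with 7 lower, such as c1qb at 50.9 against 2.02 FPKM; the list's median was 0.58 and turned to -0.00 when members had to average at least 5 FPKM.

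Lists of metabolic genes had positive medians in DBP+DiBP, the library in which 26 of 44 liver, pancreas, gut and muscle genes were higher. Of 33 genes of the aryl hydrocarbon receptor and xenobiotic metabolism 15 were higher and 1 lower (median 0.85, percentile 100), led by cyp3a65 at 49.6 against 0.509 FPKM and gsto2 at 158 against 3.88. Of 43 PPAR targets and fatty acid oxidation genes 18 were higher and 0 lower (median 0.80, percentile 100), led by FABP2 and by FABP1 at 85.5 against 2.17 FPKM. Of 41 genes of lipid and cholesterol synthesis 10 were higher and 1 lower (median 0.44, percentile 100), led by apoea at 147 against 0.501 FPKM. Both cyp3a65 and FABP2 are also markers of absorptive gut cells, and both averaged at least 1 FPKM only through DBP+DiBP. Members that enter in this way favour positive medians in that library. In DBP and DiBP the medians of these 3 lists against control lay between -0.14 and 0.05, and those of the xenobiotic list changed sign under at least 1 other scaling.

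Meiosis and spermatogonia genes had negative medians in DBP+DiBP, the library in which many gut, leukocyte and stromal genes were higher. Of 25 meiosis genes 7 were lower and 0 higher (median -0.78, percentile 0), with the recombinase DMC1 at 29.4 against 125 FPKM and the synaptonemal complex gene SYCP3 at 156 against 342. Of 10 spermatogonia genes 3 were lower (median -0.60, percentile 2.71), with PIWIL1 at 64.4 against 183 FPKM, DAZL at 77.6 against 184 and DDX4 at 167 against 352. Spermatid and flagellum genes had a median of -0.22 (percentile 45.1), with 1 of 51 higher and 1 lower, but a median of -0.82 against DBP (percentile 0; 1 higher, 14 lower) and -0.60 against DiBP (percentile 0.19; 0 higher, 6 lower). Cell cycle and DNA replication genes had a median of -0.39 (percentile 3.58), with 4 of 57 lower and 1 higher. The Leydig cell hormone insl3 was at 293 against 2072 FPKM (log2 ratio -2.82), and CYP17A1, the enzyme that makes androgen precursors, at 4.03 against 13.1 (log2 ratio -1.49). The steroidogenesis and Leydig cell list had 1 of 16 higher and 3 lower and a median of 0.20 (percentile 98.2). The Sertoli cell genes split: gsdf was at 340 against 55.0 FPKM (log2 ratio 2.61) and amh at 31.3 against 79.1 (log2 ratio -1.31), with 2 of 15 higher, 2 lower and a median of 0.32 (percentile 99.2). The 2 higher were gsdf and tfa (54.2 against 16.8 FPKM), the latter also a hepatocyte marker. Unlike in DBP, immediate early genes went both ways, 7 of 38 higher and 10 lower (median 0.08, percentile 99.6).

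Over all features, 2239 were higher and 1503 lower in DBP+DiBP than in control, and 2650 and 1161 after scaling by median ratios. The median log2 ratio was -0.11, and 0.01 after that scaling, so ratios near 0 carry no direction here. Among the highest ratios were also the proteases ctsl.1 (2703 FPKM against 0.553) and ctsbb (245 against 0.175), lgals2b (3666 against 23.9), fxyd12 (246 against 0.259), cuzd1.1 (553 against 2.44) and tspan34a (336 against 1.14), and epdl2, whose values are shared with another gene (545 against 1.38). The lowest, besides cxcl18b, PTGS2 and insl3, were nt5c2a (2.31 against 33.2), FAM167B (1.33 against 20.9), APEX1 (2.78 against 30.5), the signal recognition particle RNA rn7sl1 (55.0 against 391) and lnc.85, whose values are also shared (1.06 against 19.5).

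**Figure D1:**
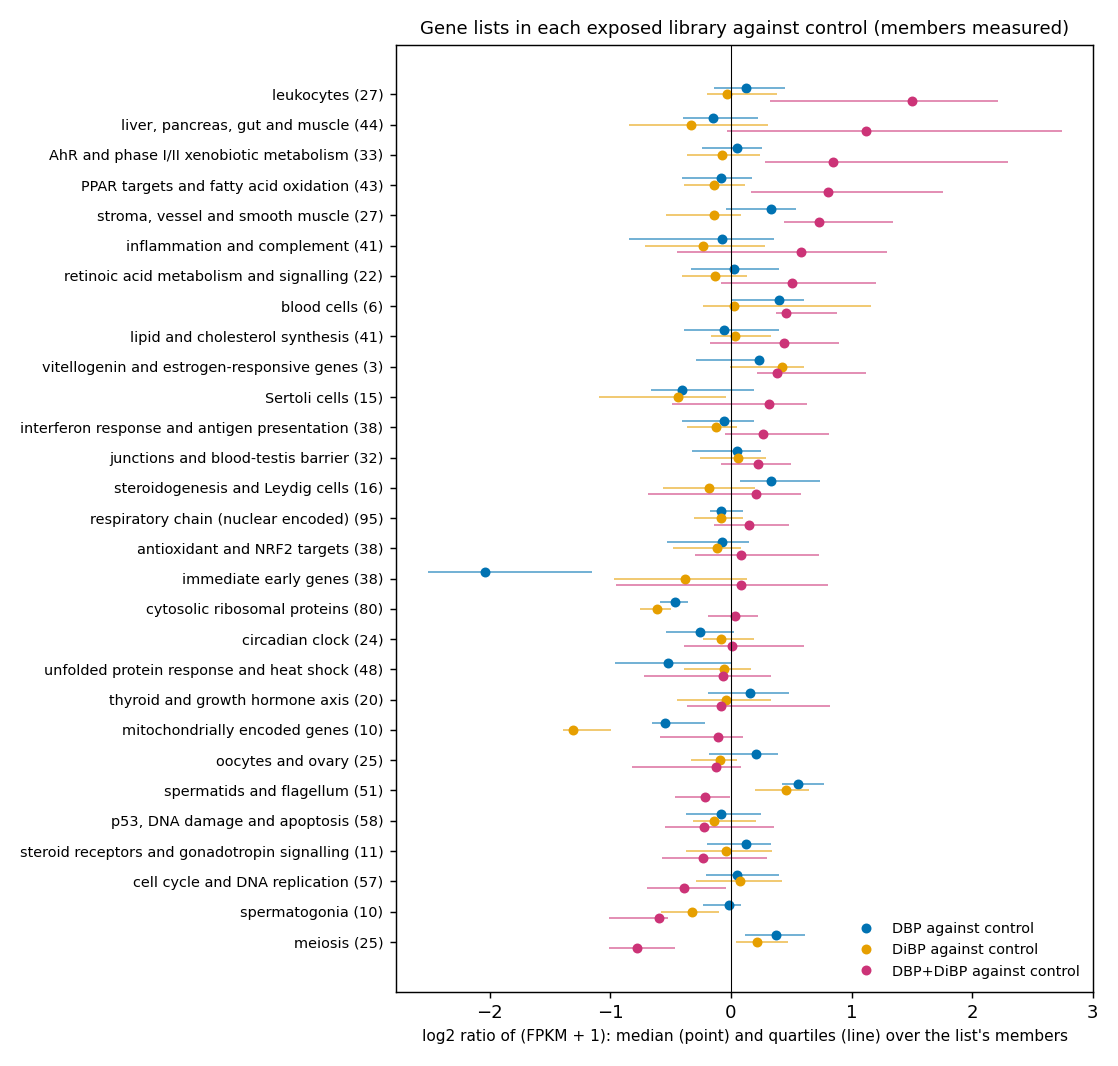
Log2 ratio of FPKM + 1 (x axis) of each exposed library to control for 29 gene lists (y axis), with points at the list median and lines from the lower to the upper quartile over the members, whose number stands in parentheses. Immediate early genes lie lowest in DBP (median -2.04), mitochondrially encoded genes lowest in DiBP (median -1.31) and leukocyte genes highest in DBP+DiBP (median 1.499).

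DiBP and DBP were compared with each other, since they are isomers, although the labels do not say whether their doses matched. Among genes with a non-provisional symbol and a mean of at least 5 FPKM, heat shock genes stood furthest apart. They were at 2342 FPKM in DiBP and 12.99 in DBP for hsp70l and at 1511 and 4.61 for hsp70.3. In a limma model of the 4 libraries with a term for each phthalate and 1 residual degree of freedom, the DiBP term minus the DBP term on the log2 scale was 7.39 for hsp70l (unadjusted 95% interval 5.48 to 9.29) and 8.08 for hsp70.3 (5.99 to 10.16), with an adjusted p of 0.445 for both. With 1 library per group, this difference of terms equals the value of the DiBP library minus that of the DBP library. The intervals here and in the next paragraph rest on departure from additivity and the prior variance, and do not measure variation between fish. Of 48 unfolded protein response and heat shock genes 12 were higher in DiBP and 0 lower (median 0.33, percentile 100), and of 38 immediate early genes 26 were higher and 0 lower (median 1.31, percentile 100), such as JUNB at 191 against 21.4 FPKM and FOS at 178 against 25.6. Steroidogenesis and Leydig cell genes were lower in DiBP than in DBP in 5 of 16 and higher in 1 (median -0.77, percentile 0). For cyp11c1 the difference was -1.47 (interval -3.18 to 0.24), for STAR -1.28 (interval -3.01 to 0.45), for insl3 -1.23 (interval -4.02 to 1.56) and for CYP17A1 -0.61 (interval -2.38 to 1.16). Mitochondrially encoded genes were lower in DiBP in 3 of 10 (median -0.84, percentile 0), and stromal genes in 4 of 27 with 1 higher (median -0.31, percentile 0).

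Other genes that set the isomers apart were MTHFS (188 FPKM in DiBP, 11.5 in DBP; difference 3.92, interval 0.87 to 6.98) and SSR1, whose values are shared with another gene (12.05 and 0.0612), both higher in DiBP. FBXO42 was lower in DiBP (0.611 against 80.8 FPKM; difference -5.67, interval -7.72 to -3.61), as were eslec (7.03 against 91.4; difference -3.53), mir202 (1.91 against 23.3; difference -3.06), FABP6 (0.430 against 10.8; difference -3.04) and spink2.6 (5.26 against 47.5; difference -2.95). FBXO42 was at 5.02 FPKM in control and 79.3 in DBP+DiBP. The isomers differed little in DMRT1, a transcription factor of male gonad development (-0.08, interval -1.97 to 1.80), gsdf (-0.08, interval -2.02 to 1.86), the estrogen receptor ESR2 (-0.08, interval -1.56 to 1.39) and amh (-0.30, interval -1.92 to 1.32), though these intervals include differences over 2-fold. In all, 621 features were higher and 1011 lower in DiBP than in DBP. The limma test of the difference called 0 of 23405 features at an adjusted p of 0.05, with 320 at an unadjusted p under 0.05, a smallest adjusted p of 0.445 and a median 95% half-width of 1.62. Among features averaging at least 5 FPKM it called 2 assembled loci, named here after their values were seen: MSTRG.26440 with 214 FPKM in DiBP and 0.229 in DBP, and MSTRG.26439 with 328 and 0.566.

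**Figure D2:**
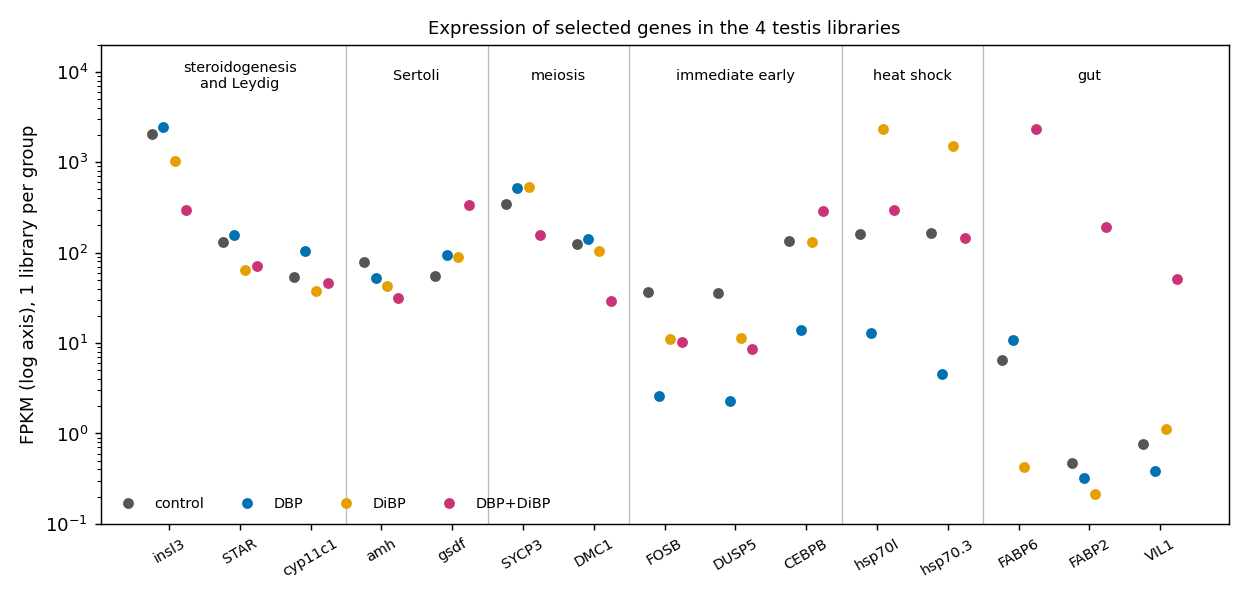
FPKM on a log axis (y axis) of 15 genes (x axis) in the 4 libraries, 1 point per library. The heat shock gene hsp70l spans 12.99 in DBP to 2342 in DiBP, and the gut gene FABP6 0.430 in DiBP to 2323 in DBP+DiBP.

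Joint exposure was also set against each single exposure. Against DBP, 2380 features were higher and 2645 lower in DBP+DiBP, with a median log2 ratio of -0.18; scaled by median ratios the split was 2941 and 1747 and the median 0.00. Against DiBP, 2446 were higher and 1917 lower with a median of -0.13, with median ratios 2898 and 1362 and a median of -0.00, and with equal library totals, which turned the balance, 2191 and 2558 and a median of -0.23. If the log2 ratios of the single exposures added up, the joint ratio would equal their sum; 3524 features lay above that sum by at least 1 and 4671 below, together 35.0% of all, with median ratios 4309 above and 3458 below, and with equal library totals 3074 and 5603. Genes far above the sum included lgals2b (by 12.33), SAA2 (by 10.30), ctsl.1 (by 10.28) and FABP6 (by 10.005), and genes below it included msnb (-7.22), mhc2dab (-6.83), endou2 (-6.21) and insl3 (-2.07). Each departure draws on 4 single libraries, so it cannot be told apart from differences between libraries. Pairs of libraries alone passed 2-fold in 6.97% (DiBP against DBP) to 21.5% (DBP+DiBP against DBP) of features. Both ctsl.1 and FABP6 are also gut cell markers, and gut tissue in the DBP+DiBP library is taken up below. For lgals2b and SAA2 the sum would lie under the lowest value that log2(FPKM + 1) can take, so part of their departure comes from that floor. The genes msnb, mhc2dab and endou2 were higher than control in every exposed library, by more in each single exposure than in the joint one.

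A set of 197 features was higher and 216 lower in every exposed library than in control; the split was 199 and 419 with no filter and 569 and 396 with pseudocount 0.1. Those with the highest mean ratios were endou2, msnb, mhc2dab, slc22a13a, taok2a, OGA, rpz5 (3.11 FPKM in control, 20.5 in DBP, 17.1 in DiBP, 34.9 in DBP+DiBP) and pnrc1 (5.996, 40.1, 61.9 and 21.0). Those with the lowest were cxcl18b (264, 7.86, 85.1 and 24.8), PTGS2 (33.3, 0.694, 11.5 and 3.29), PMP22 (28.0, 2.74, 3.101 and 4.002), TIMP2 (28.2, 0.722, 10.5 and 3.45), rn7sl1 (391, 74.6, 69.6 and 55.0), crlf1a (34.8, 4.22, 10.2 and 4.11), RND1 (18.4, 1.37, 5.61 and 2.61) and DUSP5 (35.6, 2.304, 11.4 and 8.57). Among the hormone and testis genes fixed in advance, amh was at 79.1, 52.6, 42.7 and 31.3 FPKM and gsdf at 55.0, 94.95, 89.9 and 340, and both passed 2-fold in DBP+DiBP alone. DMRT1 was at 105, 112, 106 and 54.4 FPKM. The expressed ESR2 copy was at 2.71, 4.44, 4.13 and 4.96. ESR1, CYP19A1, lhcgr, FSHR, HSD17B3, PPARA and the other ESR2 copy stayed under 1 FPKM in every library, and CYP1A1 was at 0.285, 0.512, 0.197 and 2.104. The gene hsd3b2 was at 0.754, 0.401, 1.16 and 0.130 FPKM, the SOX9 copies at 0.214, 0.713, 0.718 and 0.859 and at 0.731, 1.104, 0.542 and 1.73, and the vitellogenin feature vtg5, shared by several gene copies, at 0.257, 0.414, 0.305 and 0.368. No gene carried the symbol cyp11a2.

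A set of this kind also arises by taking another library as the odd one out, with 547 features for DBP, 214 for DiBP and 1927 for DBP+DiBP, against the 413 that set control apart. In limma with Benjamini-Hochberg adjustment, control against the 3 exposed libraries gave 0 called features of 23405 (678 at an unadjusted p under 0.05; smallest adjusted p 0.401; median 95% half-width 1.099). The additive DBP term gave 0 (450 at an unadjusted p under 0.05; smallest adjusted p 0.869) and the additive DiBP term 0 (326; 0.479). With pseudocount 0.1 the first of these fits called 2 assembled loci, MSTRG.34757 (listed at 0 in control, then 26.9, 32.6 and 34.03 FPKM) and MSTRG.39473 (0, then 29.9, 36.8 and 35.9), named after their values were seen. The loci numbered next to them were not at 0 in control: MSTRG.34756 was listed at 30.9 in control, 0 in DBP, 5.50 in DiBP and 34.02 in DBP+DiBP, and MSTRG.39474 at 32.2, 29.9, 36.8 and 0, each within 1% of its neighbour in at least 1 library, so the calls do not show expression absent from control. The same limma test on DBP+DiBP against the other 3 libraries called 685 features, 646 higher and 39 lower (4384 at an unadjusted p under 0.05; smallest adjusted p 0.00815), assuming that the lone library varies like the others; DBP against the other 3 gave 0 (923) and DiBP against the other 3 gave 0 (302). Leaving out DBP, DiBP or DBP+DiBP changed the shared set from 413 to 643, 700 or 1008, as fewer libraries had to meet the rule.

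The ratios of DBP and DiBP to the same control correlated across genes with r of 0.615, where unchanged libraries simulated against a shared control gave 0.5003. The simulation drew each feature with its SD over all 4 libraries, DBP+DiBP included, so its noise holds any differences between exposures. It also gave every library the same noise, which by itself sets its r near 0.5. Its r, covariance, counts and share of like sign are therefore not a chance level for these pairs. Their covariance was 0.276, and 0.303 in the simulation. The features past 2-fold the same way in both numbered 1008 (572 higher, 436 lower), where independent lists would share 113. In the simulation they numbered 1162 (554 higher, 609 lower), where independent lists would share 189.9. Of the features past 2-fold in DBP, 87.5% had the same sign in DiBP, and 80.2% in the simulation. DBP and DBP+DiBP gave r of 0.261 and 700 shared features, and DiBP and DBP+DiBP 0.248 and 643, beside 1162 and 1161 in the simulation. Taking another library as the reference also gave correlated ratios. Over the pairs, r ranged from 0.333 to 0.534 with DBP as reference, 0.262 to 0.413 with DiBP and 0.735 to 0.823 with DBP+DiBP. With 1 control library the control cannot be split, so how much of each overlap comes from the shared control is not known.

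**Figure D3:**
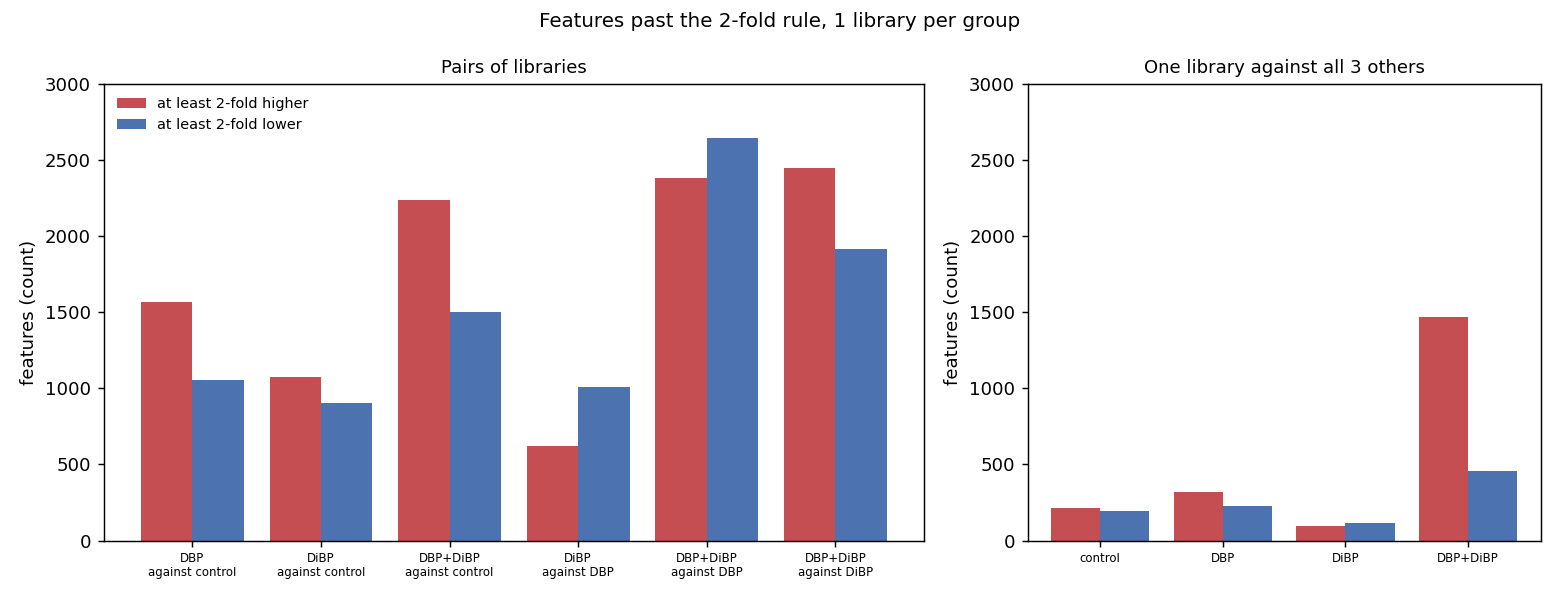
Number of features at least 2-fold higher or lower (y axis) for the 6 pairs of libraries (left) and for each library against all 3 others at once (right), 1 library per group. DBP+DiBP differs from the other 3 in 1927 features, and control in 413.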

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

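The alternatives with Ensembl genes only, without merged features, without immediate early and heat shock genes, and with a filter that ignores the DBP+DiBP library were chosen after the results were seen. Counts are given in this order: DBP, DiBP and DBP+DiBP against control, DiBP against DBP, DBP+DiBP against DBP and against DiBP, the set shared by all exposed libraries, and departures from additivity. Under the 3 other scalings, without merged features, without immediate early and heat shock genes, and with no filter, each of these counts stayed within 1.5 times its reported value. With the filter that ignores DBP+DiBP, 2687, 2034 and 1668 features passed for DBP and DiBP against control and DiBP against DBP. A mean of at least 5 FPKM gave 1021, 854, 1597, 640, 2355, 2001, 179 and 3849, and Ensembl genes only gave 1262, 989, 2270, 718, 3037, 2758, 181 and 5202, both with fewer features to count. Pseudocount 0.1, which shrinks low values less, gave 4530, 3974 and 6020 against control, 3258 for DiBP against DBP, 6717 for DBP+DiBP against DiBP and 965 for the shared set, while the other counts stayed within 1.5 times. Leaving out each exposed library in turn gave a shared set of 643 to 1008, as fewer libraries had to meet the rule. The shared set's split of 197 higher and 216 lower became 199 and 419 with no filter and 569 and 396 with pseudocount 0.1.

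The limma fits of control against the exposed libraries, of the additive terms and of their difference called 0 features under every alternative run except 2 for control against the exposed libraries with pseudocount 0.1 and 2 for DiBP minus DBP at a mean of at least 5 FPKM; the cause was not tested. The fits of DBP, DiBP or DBP+DiBP against the other 3 libraries were not run under alternatives. For control against the exposed libraries, unadjusted p under 0.05 was met by 425 features without DBP, 420 without DiBP and 2267 without DBP+DiBP, beside 678 with all. The median of the inflammation and complement list, DBP+DiBP against control, turned from 0.58 to -0.00496 when members had to average at least 5 FPKM; fewer members were then counted. Of the 116 list medians, 14 others moved by more than 0.25 under that filter, and 20 in all changed sign. All 212 log2 ratios of named genes and all 116 list medians moved by under 0.25 under each of the 3 scalings, although up to 15 list medians and 2 named ratios near 0 changed sign. Pseudocount 0.1 moved 98 named ratios and 6 medians by more, none reversed in sign. Not run for lack of counts were the DESeq2 Wald test, limma-voom, prior counts of 0.5 and 10, and counting intervals. No paired analysis was possible because each group was 1 library, so that no number pairs more than 1 library per group. Read depth is known only relative to control, so no floor or counting interval can be given, and 1 library per group limits every comparison.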

Other observations

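Of the tests below, that of gut tissue and that of exposure for features with a high and a low level were written down before their results were seen, and all other tests were chosen after. In DBP, circadian clock genes had a median log2 ratio to control of -0.25 (percentile 0.45), with 2 of 24 lower, among them the repressor nr1d2a at 1.25 against 4.69 FPKM. Steroid receptor and gonadotropin signalling genes had medians of 0.13, -0.04 and -0.23 in DBP, DiBP and DBP+DiBP, the second changing sign under another scaling; the activin subunit INHBA was lower in each (1.33, 1.77 and 0.984 FPKM, control 5.18), and follistatin, FST, was at 1.48 against 7.98 in DBP+DiBP. Of the 25 oocyte and ovary genes, 3 were higher and 1 lower in DBP, 1 higher and 2 lower in DiBP, and 1 higher and 6 lower in DBP+DiBP; DAZL, counted there too, is also a germ cell gene of the testis. The 3 measured vitellogenin and estrogen-responsive genes had 1 past 2-fold, CTSD at 223 against 60.6 FPKM in DBP+DiBP. The retinoic acid hydroxylase CYP26A1 was higher in every exposed library (24.3 in DBP, 26.2 in DiBP and 42.7 in DBP+DiBP, control 6.17), and in that list 8 of 22 were higher and 2 lower in DBP+DiBP (median 0.51, percentile 99.95), the library in which 25 of 28 absorptive enterocyte and 14 of 18 hepatocyte markers were higher than control.

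Interferon and antigen presentation genes were higher in 4 of 38 and lower in 2 in DBP, 3 and 1 in DiBP, and 6 and 1 in DBP+DiBP, with ifit8 at 13.5 and 13.8 FPKM in DBP and DiBP against 1.40 in control. In DBP+DiBP, where absorptive enterocyte markers had a median of 3.35 against control, the antioxidant list had 8 of 38 higher and 1 lower (median 0.09, percentile 99.6), with prdx6 at 281 against 44.0 FPKM. The nuclear respiratory chain list had 9 of 95 higher and 1 lower (median 0.15, percentile 100), with cox4i1l, 1 of the genes that set this library apart from the others, at 216 against 10.9 FPKM. Junction and blood-testis barrier genes had 3 of 32 higher and 1 lower in DBP+DiBP (median 0.22), thyroid and growth hormone axis genes 3 of 20 higher and 1 lower (median -0.08, which changed sign under another scaling), and blood cell genes 1 of 6 higher (median 0.46).

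In DBP+DiBP, 1468 features lay at least 2-fold above all 3 other libraries. The gut cell lists that follow were written after the first results were seen. Of the lysosome-rich enterocyte markers, ctsl.1, FABP6, ctsbb and tspan34a were already among the highest ratios of this library. That list's median and count are therefore partly read back from the data. Against the mean of the other libraries, absorptive enterocyte markers had a median of 3.48 (24 of 28 higher; 4 also reach 5 FPKM in another library and 9 are in a list above) and lysosome-rich enterocyte markers 3.76 (16 of 20 higher; 13 reach 5 FPKM elsewhere), with ctsl.1 at 2703, FABP6 at 2323, LGMN at 645 and apoa1a at 461 FPKM. The tables argued against scaling as the cause, since at least 94.96% of the features kept that margin under each of 3 other scalings, and against a lower share of germ cells alone, since the medians of Leydig, Sertoli, stroma and leukocyte lists (-0.24, 0.51, 0.82 and 1.26) spread over 1.501 instead of moving together. Intestinal tissue in the sample may account for part of the pattern. Intestinal transcription factors (median 1.32, 9 measured), goblet (1.15, 6 measured) and enteroendocrine markers (0.75, 18 measured) had positive medians. Together their median was 1.14 (18 of 33 higher, 1 lower, 9 reaching 5 FPKM elsewhere). This cannot decide it, because members of each list had to average at least 1 FPKM over all 4 libraries. NR1H4, insl5b, PYY, sst2, penka and foxa3 passed only through DBP+DiBP, which favours positive medians, while the matched cdx1b, hnf4a and muc2.2 did not pass. Many absorptive enterocyte markers, such as FABP2, chia.2 and VIL1, also passed only through DBP+DiBP. Members reaching 5 FPKM elsewhere went both ways, for example AGR2 at 4.65 and PAX6 at -0.97. Pancreatic acinar (1.498, 11 of 16 higher, 10 in a list above, 10 reaching 5 FPKM elsewhere) and hepatocyte markers (2.21, 14 of 18 higher, 11 in a list above, 5 reaching 5 FPKM elsewhere) had positive medians. Skeletal muscle markers did not (-0.63, 2 of 19 higher and 5 lower), and stood at -0.13 against control alone, as they were higher in DiBP. An effect of joint exposure on these genes stays open, as the group is this 1 library.

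Immediate early genes were lower in DBP than in control, at a median of -2.04. The values argued against scaling as the cause, since at least 96.9% of the 32 lower members stayed 2-fold lower under each of 3 other scalings. A different mix of cell types would have to lower the cells that carry these genes by a like amount. The lowest median among stroma, leukocyte and Sertoli lists was -0.40, so no loss of that size was seen in these lists. The values do not show which cells carry the immediate early genes, so a different mix of cell types stays open. Tissue handling before freezing, which may induce such genes, cannot be told apart from DBP exposure, because 0 of 4 samples' labels give a time or order of dissection. An effect of DBP stays open as untested.

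Some features fell into a high and a low level across libraries, 185 in all among those averaging at least 5 FPKM. The gap was at least 3 on the log2 scale, with a range of at most 1 within each level. The low level was not always near 0: LGMN was at 24.8, 27.7 and 27.9 FPKM in control, DBP and DiBP and at 645 in DBP+DiBP. Of these 148 set DBP+DiBP apart, 10 set control apart from the 3 exposed libraries, 10 DBP and 5 DiBP, and the splits into pairs held 6, 3 and 3. For 6 of the 10 that set control apart, all assembled loci, the locus numbered next to them had values within 1% in at least 1 library and was listed where they were near 0, so that the higher of both stayed within 2-fold over the 4 libraries (MSTRG.39473 and MSTRG.39474, for example, at 0 and 32.2 FPKM in control). These 6 may reflect which of 2 neighbouring loci the expression was listed under, not genes switched by exposure; such a neighbour was found for 3.23% of assembled loci with a mean of at least 5 FPKM. Without loci of this kind 4 features set control apart, 7 DBP and 4 DiBP, so for these exposure to either phthalate cannot be told apart from differences between fish or pools of fish, with 1 library per group.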
